A study of Mus musculus with 2 samples.

How the data were processed

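Total RNA-seq was measured in adrenal glands of B6CASTF1/J female mice, the F1 hybrids of a C57BL/6J and a CAST/EiJ parent, at 10 days of age. Per the labels, each library was made from 300 ng of RNA with a directional kit after reduction of ribosomal RNA, and ERCC spike-in RNA was added. The series holds 1 group with 2 libraries, numbered replicate 1 and replicate 2 as biological replicates in the labels. The labels name a different female for each tissue sample but repeat the same female and the same cDNA number in the descriptions of both libraries, with 1 donor entry for both. Whether n = 2 stands for separate animals is therefore open. SDs and the coefficient of variation measure only the spread between these 2 samples, which can be technical, and p-values of the exact test measure counting error only.

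Each library came with a gene table and a transcript table of the same quantification and with a transcript table of another quantification. The gene table and its transcript table hold expected counts, TPM, FPKM and credibility intervals of TPM (a signal range), deposited by the authors with the column names of RSEM. The percent of a gene's TPM in each transcript was deposited in the same transcript table. The other table holds estimated counts and TPM, deposited by the authors with the column names of kallisto. Per the file headers and the notes deposited with them, the assembly was mm10 and the annotation M21. The names and versions of the aligner and of both quantifiers are not given in the sources used here. The TPM values of the deposited gene table are scaled over all features, spike-ins included. Whether counting used the strand, and whether CAST/EiJ variants were taken into account, is not given in the sources used here, so overlapping and antisense genes are uncertain. In the first quantification the effective length of a transcript was its length minus a median of 99 nt, and in the other it was shorter by a median of 324.06 nt in replicate 1 and 327.06 nt in replicate 2, both over longer transcripts.

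All 55536 gene IDs of the gene table matched the annotation, from which symbols, gene types and coordinates were taken. The gene table also holds 96 ERCC sequences, a phiX sequence with 0 counts and 26248 features with a bare number as ID. The numbered features took 1.96e-05% of the counts in replicate 1 and 1.8e-05% in replicate 2 and stayed out of library sizes and tests. The total expected count was 35636846 in replicate 1 and 33378436 in replicate 2. A count of 0 allows up to 3 counts, which is 0.0842 and 0.0899 CPM in replicates 1 and 2. Intervals and this limit cover counting error only, since no molecular identifiers are stated.

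The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 31 lists hold 383 distinct genes, and 2 list symbols (Ahsp and Rn7sl1) had no ID in the annotation. The named genes are the 4 members with the highest mean TPM in each list and every member of lists of up to 6 genes, the 10 genes with the highest mean TPM, the 10 genes with the largest log2 ratio in each direction among those past the threshold with a mean count of at least 100, the 5 genes in each direction that differ most between the quantifications, the genes of 8 paired ratios, and up to 5 steroid or chromaffin genes whose dominant transcript differs between quantifications. Other genes that are named were chosen after their values were seen, and they are marked as such where they stand. Some genes that the rule names are not reported here.

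A gene was called detected at a TPM of at least 1 in both libraries. Levels are given as the mean and SD of TPM over the 2 libraries. Expected counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16, run in R 4.3.3. The common dispersion came from an intercept-only design. With 1 group there is no contrast for the edgeR quasi-likelihood test, and sign flips over 2 libraries cannot go below an exact two-sided p of 0.5, so no test over animals was run. Differences between the libraries were tested per gene with an exact two-sided binomial test on genes with a summed count of at least 20, with Benjamini-Hochberg adjustment at 0.05 and at least 2-fold. This test compares the 2 libraries and has no replicate check. Log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5. Ratios carry exact 95% Clopper-Pearson intervals. The median log2 ratio of each list was set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Correlations were computed across genes, which are not replicates, on log2(TPM + 1), in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Mitochondrial mRNAs were compared with annotated pseudogenes with blastn 2.17.0.

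The steps were tested on simulated data. For the comparison between the libraries, run on 18883 genes, the exact test recovered 100% of 100 genes changed 3-fold and 100% of 100 genes changed 8-fold, and it called 0% of the unchanged genes under pure counting error. The changed genes were drawn only from genes with higher counts, and the true library sizes were used. Recovery at low counts, with TMM scaling or with spread beyond counting error was therefore not tested. Simulated dispersions of 0.01 and 0.05 were estimated at 0.0101 and 0.0500. A simulated list shifted by 1.5 gave a median of 1.47, and an unshifted list gave -0.01.

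Alternatives covered other TPM minimums, FPKM, posterior mean TPM, the other quantification, TPM without spike-ins and mitochondrial genes, pseudocounts, total count, DESeq2 1.42.0 and ERCC scaling, count filters, a negative binomial test with the common dispersion, fold limits, 50 bins and each library alone. The gene annotation includes near-identical copies such as Hba-a1 and Hba-a2, the histone genes, and Rn7s1 and Rn7s2. It also includes related genes such as Cyp11b1 and Cyp11b2, whose identity was not measured. Reads that such copies or related genes share were divided by the authors' quantifiers, and the split between them is uncertain.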

Results

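Total RNA of the adrenal gland was sequenced from 10-day-old B6CASTF1/J female mice in 2 libraries of 1 group. The libraries held 35636846 and 33378436 expected counts for replicates 1 and 2. In replicate 1, 14948 genes reached a TPM of 1, and 14684 did so in replicate 2. There is no second condition, so the values describe this tissue and the spread between the libraries.

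The X-linked transcript Xist, which coats the inactive X chromosome, stood at 71.5 ± 4.79 TPM (SD, n = 2), and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 or 1 counts in each library. Those counts lie under the 3 counts that a count of 0 allows. Xist lies on chromosome X from 103460366 to 103483254 in mm10. In the other quantification Uty was listed at a mean of 1.17 TPM and Kdm5d at 0.408 TPM. Gm47283, also placed on chromosome Y by the annotation, was listed there at a mean of 163 TPM and at 0 in the gene table. Whether its reads came from chromosome Y was not tested.

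Which genes an adrenal gland of this age expresses was addressed through gene levels. Genes of steroid synthesis in the cortex were abundant. Hsd3b1, which makes progesterone from pregnenolone, reached 1440.2 ± 22.5 TPM (SD, n = 2) and ranked 6 among nuclear protein-coding genes. Cyp21a1, the steroid 21-hydroxylase, stood at 831 ± 18.7 TPM, Star, which brings cholesterol into mitochondria, at 698 ± 178 TPM, and Cyp11a1, the side-chain cleavage enzyme, at 527 ± 15.3 TPM. All 17 genes of the steroid synthesis list were detected in both libraries, and 16 had at least 10 TPM in both. The median of the list was 98.3 TPM in replicate 1 and 104.6 TPM in replicate 2. Hsd3b1 (ENSMUSG00000027871.16 in the annotation) lies on chromosome 3 from 98852194 to 98859794, Cyp21a1 on chromosome 17 from 34801348 to 34804561, Star on chromosome 8 from 25806555 to 25815982 and Cyp11a1 on chromosome 9 from 58006411 to 58027023.

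Markers of the cortical zones were present at unequal levels. Of the zona glomerulosa genes, the potassium channel gene Kcnk3 stood at 183 ± 1.90 TPM, Dab2 at 123 ± 6.84 TPM, the angiotensin receptor gene Agtr1a at 41.8 ± 0.559 TPM and the aldosterone synthase gene Cyp11b2 at 29.1 ± 4.19 TPM. All 9 glomerulosa genes were detected in both libraries. Of the zona fasciculata genes, Cyp11b1, the 11-beta-hydroxylase of corticosterone synthesis, reached 372 ± 16.6 TPM, Mrap 80.2 ± 11.7 TPM, Abcb1b 58.4 ± 6.07 TPM and the ACTH receptor gene Mc2r 42.8 ± 0.431 TPM. Akr1b7 was 47.3 TPM in replicate 1 and 122.7 TPM in replicate 2. Among the X-zone markers Akr1c18, which inactivates progesterone, stood at 159 ± 34.0 TPM, Thrb at 11.8 ± 0.396 TPM and Pik3c2g at 1.07 ± 0.0212 TPM. Genes of the adrenal capsule and stroma included Col1a1 at 329.9 ± 110.5 TPM, Col1a2 at 224 ± 60.4 TPM, Dcn at 93.5 ± 2.76 TPM and Nr2f2 at 29.4 ± 4.35 TPM.

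Cholesterol supply genes and cortical transcription factors were expressed alongside. Scarb1, the receptor for HDL cholesterol, stood at 199.8 ± 46.5 TPM, the hormone-sensitive lipase gene Lipe at 143 ± 20.2 TPM, Soat1, which esterifies cholesterol, at 117 ± 0.191 TPM and Hmgcs1 at 87.4 ± 2.45 TPM. All 21 genes of that list were detected in both libraries. Nr5a1, the steroidogenic factor, reached 78.0 ± 7.27 TPM, and 11 of the 12 transcription factors were detected in both libraries. The gonadal list had 1 detected gene of 10, Insl3 at 3.28 ± 0.424 TPM, with Cyp17a1 at 1.07 ± 0.898, Sox9 at 0.485 ± 0.120 and Hsd17b1 at 0.280 ± 0.0849 TPM.

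The catecholamine-producing chromaffin cells of the medulla were also represented. The granule protein genes Chga and Chgb stood at 330.6 ± 23.6 and 279.7 ± 20.1 TPM (SD, n = 2), the adrenaline-forming enzyme gene Pnmt at 175 ± 41.1 TPM and the neuropeptide gene Npy at 155 ± 17.5 TPM. All 16 chromaffin genes were detected in both libraries, and 11 had at least 10 TPM in both. The neuronal list was lower, with Stmn2 at 30.3 ± 5.09, Tubb3 at 20.9 ± 5.37, Prph at 16.3 ± 4.45 and Gap43 at 12.8 ± 1.77 TPM. Schwann and sustentacular genes had S100b at 23.2 ± 4.69, Mbp at 7.92 ± 0.997 and Fabp7 at 4.78 ± 0.672 TPM. Chga lies on chromosome 12 from 102554969 to 102565028 and Pnmt on chromosome 11 from 98386450 to 98388181.

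Genes of fat cells were among the most abundant mRNAs in both libraries. Fabp4, the fatty acid carrier of adipocytes, stood at 1728 ± 274 TPM, Car3 at 584 ± 2.49 TPM, the lipid droplet gene Plin1 at 305 ± 1.94 TPM and Adipoq at 147 ± 1.55 TPM. Ucp1, the uncoupling protein of brown fat, reached 1139.9 ± 229 TPM, Cox8b 1040.7 ± 84.4 TPM, Cox7a1 556 ± 32.2 TPM, Cidea 489 ± 62.5 TPM, Cpt1b 229 ± 16.3 TPM and Elovl3 2.17 ± 0.240 TPM. All 6 brown fat genes and all 8 general fat genes were detected in both libraries. Whole tissue was measured, so which cells these RNAs came from, inside the gland or beside it, was not tested. The same holds for the genes of the other lists.

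**Figure D1:**
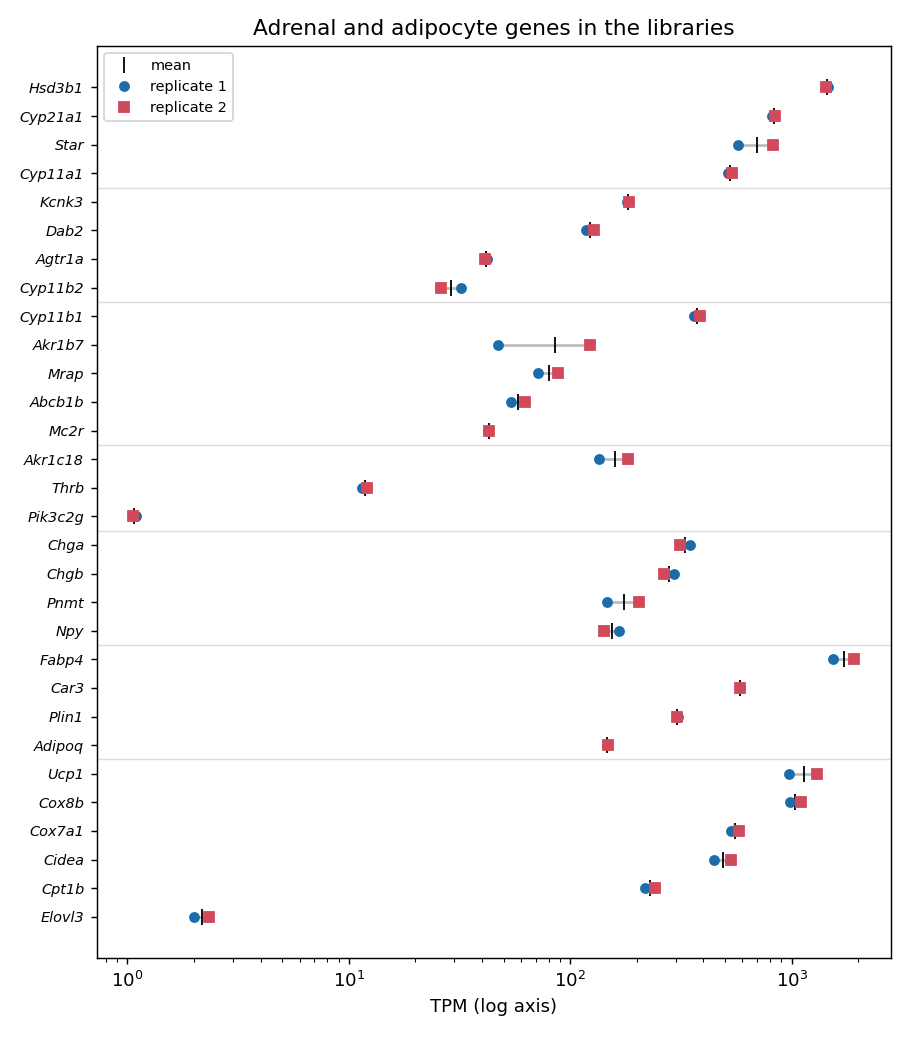
TPM on a log axis of the named genes of the steroid, zone, chromaffin and fat lists, with a circle for replicate 1, a square for replicate 2 and a tick for their mean. Akr1b7 lies at 47.3 TPM in replicate 1 and at 122.7 TPM in replicate 2.

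Red cell genes were abundant, with Hba-a1 at 1242 ± 479 TPM and Hbb-bs at 1169 ± 415 TPM. Endothelial genes included Egfl7 at 95.8 ± 6.19, Cdh5 at 65.2 ± 3.84, Pecam1 at 49.5 ± 1.85 and Kdr at 35.6 ± 0.417 TPM, and all 10 were at least 10 TPM in both libraries. Macrophage genes had Lyz2 at 31.2 ± 5.25, Csf1r at 10.6 ± 1.77, C1qb at 8.93 ± 1.38 and C1qa at 8.79 ± 1.23 TPM. Of the cell cycle genes, 18 of 18 were detected in both libraries, with Pcna at 36.9 ± 1.18, Top2a at 23.2 ± 1.29, Mcm6 at 21.7 ± 0.502 and Cdk1 at 17.5 ± 1.33 TPM. Circadian genes included Tef at 25.7 ± 1.75, Per1 at 24.6 ± 5.34, Dbp at 17.1 ± 4.96 and Nr1d2 at 16.3 ± 1.07 TPM. Glucocorticoid-related genes had Tsc22d3 at 33.9 ± 5.93, Sgk1 at 33.7 ± 3.32 and the glucocorticoid receptor gene Nr3c1 at 27.9 ± 0.368 TPM. The histone list had Hist1h4h at 341 ± 14.1, Hist2h2aa2 at 329.8 ± 33.7, Hist1h4k at 241 ± 40.7 and Hist2h3b at 200.1 ± 35.1 TPM. None of the 8 pancreas genes was detected, with Ctrb1 at 0.265 ± 0.318, Amy2a5 at 0.10 ± 0.0566, Cela3b at 0.0800 ± 0.0566 and Cpa1 at 0.0700 ± 0.0707 TPM.

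Non-coding and mitochondrial RNAs were the most abundant in the gene table. The list of abundant non-coding RNAs took 27.6 ± 0.961% of TPM there and a mean of 0.197% in the other quantification. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA on chromosome 12, were each listed at 108026 ± 4459 TPM with the same value in both copies. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 94990 ± 5406 and 66446 ± 4646 TPM, and Rn7sk at 43752 ± 1081 TPM. Rpph1 stood at 6820.4 ± 249 TPM, below the 10 most abundant genes. The remaining genes among the top 10 included mt-Co1 at 14957 ± 903 TPM and mt-Cytb at 8614 ± 945 TPM. Gm26917, which the annotation lists as a lincRNA gene, stood at 12753 ± 395 TPM. Which RNA its reads came from was not tested. The others were the chromosome 1 pseudogenes Gm28661 and Gm10925 at 16555 ± 1337 and 12073 ± 1751 TPM. Both pseudogenes are near-identical to mitochondrial genes, so the division of reads is uncertain. The 15 mitochondrially encoded genes summed to 22.9 ± 1.60% of all TPM.

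A total of 14179 genes were detected in both libraries, of which 12813 were protein-coding and 160 were lincRNA genes. At 10 TPM or more in both libraries there were 6503 genes, and at 100 TPM or more there were 619.

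Ratios of paired genes were taken within each library, and only some of the pairs compared zones or lineages. Cyp11b1 exceeded Cyp11b2 by a log2 ratio of 3.69 ± 0.27 (SD, n = 2), Hsd3b1 exceeded its glomerulosa paralog Hsd3b6 by 6.92 ± 0.05 and Agtr1a exceeded Agtr1b by 3.85 ± 0.07. Th, the tyrosine hydroxylase gene, lay below Star with a log2 ratio of -2.44 ± 0.47, and Cyp17a1 lay below Cyp11a1 with -9.25 ± 1.34. mt-Rnr2 exceeded mt-Co1 by 2.67 ± 0.01. These 6 differences were larger than the spread between the libraries. Pnmt over Th came to 0.44 ± 0.44, about the size of the spread. Hsd11b1 over Hsd11b2 was 4.27 in replicate 1 and -0.45 in replicate 2, so no common direction was found. An exact test over 2 libraries cannot go below p = 0.5, and none was run.

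The libraries were then compared with each other. Across the 14179 detected genes, including Hsd3b1, Cyp21a1 and Cyp11a1 with nearly equal levels, Pearson's r of log2(TPM + 1) was 0.979 and Spearman's rho was 0.973, both across genes, which are not independent replicates. Of these genes 96.6% lay within 2-fold. The 1274 genes with a TPM of at least 1 in 1 library only are left out of these values, as are the 10 kidney list genes. The common dispersion corresponded to a biological coefficient of variation of 0.282. The chi-square of the counts over 18883 genes was 60.1 per gene, above the value of about 1 that sampling noise gives. The files therefore do not hold 1 library deposited again, which leaves open whether the libraries came from separate animals.

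Genes of the liver, kidney and skeletal muscle lists differed between the libraries. Alb, the serum albumin gene of hepatocytes, was 4.81-fold higher in replicate 1 (95% interval 4.75 to 4.86), at 2509 against 502 TPM. Slc34a1, a phosphate transporter of the proximal tubule, was 1018-fold higher in replicate 2 (95% interval 468 to 2776), at 80.8 against 0.14 TPM. The muscle actin gene Acta1 was 3.50-fold higher in replicate 1 (95% interval 3.43 to 3.56), at 1194 against 328 TPM. Alb lies on chromosome 5 from 90460897 to 90476602, Slc34a1 on chromosome 13 from 55398187 to 55415592 and Acta1 on chromosome 8 from 123891769 to 123894751.

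All 8 liver genes were higher in replicate 1 by the exact binomial test, with a median log2 ratio of -2.28, which lay outside the central 95% of random lists. Trf, Ahsg and Apoa1, which encode secreted plasma proteins, were 4.89-fold, 5.50-fold and 5.25-fold higher there. All 10 kidney genes were higher in replicate 2, with a median of 8.38, or 8.23 with the gene at 0 counts set to the limit of 3 counts per library. Kap stood at 70.2 TPM in replicate 2 and 0.20 in replicate 1, Lrp2 at 22.3 and 0.37, and Slc12a3 at 21.7 and 0.08. In the other quantification the kidney median was 7.12. Of the 8 skeletal muscle genes, 7 were higher in replicate 1 and 1 in replicate 2, with a median of -1.73. Mylpf, Tnnt3 and Ckm had log2 ratios of -1.45, -1.89 and -1.08, while Myh4, chosen after its value was seen, was 10.3-fold higher in replicate 2.

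In the erythroid list 4 of 9 compared genes passed the threshold toward replicate 1, and the median was -0.82. Among them, chosen after their values were seen, were Slc4a1, Hemgn and Epb42, with log2 ratios of -2.15, -3.00 and -2.29. The globin genes Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt did not pass it, with log2 ratios of -0.77, -0.68, -0.63 and -0.82. Of the 9 compared lymphocyte genes 4 were higher in replicate 1, and the median was -0.85. Among them were Cd3e at -1.67 and, chosen after their values were seen, Cd3g and Ms4a1 at -1.42 and -1.51. Ighm, Cd79b and Cd79a stood at -0.85, -0.77 and -0.69 without passing. The liver list, at -2.28, went the way of the erythroid and lymphocyte genes.

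None of the 17 steroid synthesis genes and none of the 16 chromaffin genes passed the threshold, and their medians were 0.11 and -0.08. Within the steroid synthesis list the log2 ratios ran from -0.24 to 0.62, with 14 genes above 0 and 3 below. Star lay at 0.53 to 0.62 over the alternatives run, so levels within 2-fold were not all equal. The steroid synthesis median lay inside the central 95% of random lists and the chromaffin median outside. In the fasciculata list 1 of 5 genes passed, Akr1b7, which was 2.70-fold higher in replicate 2 (95% interval 2.56 to 2.85), and the median was 0.36. Col1a1 and Col1a2 had log2 ratios of 0.76 and 0.62 in the capsule and stroma list, whose median was 0.34, with 1 of 10 genes past the threshold, Wt1 at 1.02, named after its value was seen. The kidney list, at 8.38, went the way of Wt1, which podocytes of the kidney also express. The glomerulosa median was -0.04 and the X-zone median 0.15, with 0 calls in each. Cyp17a1 was 4.48-fold higher in replicate 2, from 21 and 84 counts, and the gonadal median was 0.06. Other medians were 0.17 for the transcription factors, of which Nr4a1 and Wt1 passed, 0.10 for cholesterol genes, 0.27 for brown fat genes with 0 calls, 0.15 for general fat genes with 1 call, Retn at 1.59, named after its value was seen, 0.16 for endothelial, -0.19 for macrophage, -0.22 for neuronal and -0.22 for Schwann genes.

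Nr4a1, an orphan receptor gene induced early by stimulation, was 2.53-fold higher in replicate 2, and the immediate early list had a median of 0.47 with 2 of 14 genes past the threshold. The other was Fos at 1.47, named after its value was seen. Jun, Dusp1 and Junb had log2 ratios of 0.07, 0.47 and 0.97. Among imprinted genes H19 and Igf2 were 4.06-fold and 2.74-fold higher in replicate 1, the other 19 compared genes did not pass, and the median was -0.16. The liver and skeletal muscle lists, at -2.28 and -1.73, were also higher in replicate 1. Gnas stood at 2041.2 ± 44.0 TPM and Meg3 at 326 ± 104 TPM. Agt, which encodes angiotensinogen, was 4.76-fold higher in replicate 1 while Agtr1a and Agtr2 had log2 ratios of 0.13 and -0.48, and the renin-angiotensin median was 0.10. Ren1, named after its value was seen, was 56.3-fold higher in replicate 2. The liver list, at -2.28, went the way of Agt, and the kidney list, at 8.38, the way of Ren1 and Hsd11b2. Hsd11b1 was 2.61-fold higher in replicate 1 and Hsd11b2 10.3-fold higher in replicate 2, in a list with a median of 0.28, where Zbtb16 at 1.23, named after its value was seen, also passed. The medians were 0.10 for clock genes, -0.05 for cell cycle genes, 0.20 for mitochondrial genes, 0.01 for abundant non-coding RNAs and -0.14 for histone genes. The histone genes past the threshold were Hist1h2ao, listed at 0 and 25.2 TPM in replicates 1 and 2, and, named after their values were seen, Hist2h3c1 at 2.74 and Hist1h4n at -1.05. All have near-identical copies and credibility intervals that overlap between the libraries. In the other quantification Hist1h2ao stood at 1.19 and 1.74 TPM, Hist2h3c1 at 5.66 and 4.55 TPM and Hist1h4n at 2.05 and 2.23 TPM, so these differences are uncertain. The medians near 0 changed sign with the setting. The gonadal median was -0.01 with total count scaling, the glomerulosa median was 0.01 in the other quantification, and that of the abundant non-coding RNAs was -0.06 and -0.10 in the same settings. Over all alternatives run the gonadal median reached up to 0.66. The pancreas and sex-chromosome lists had fewer than 3 genes with enough counts for a median.

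**Figure D2:**
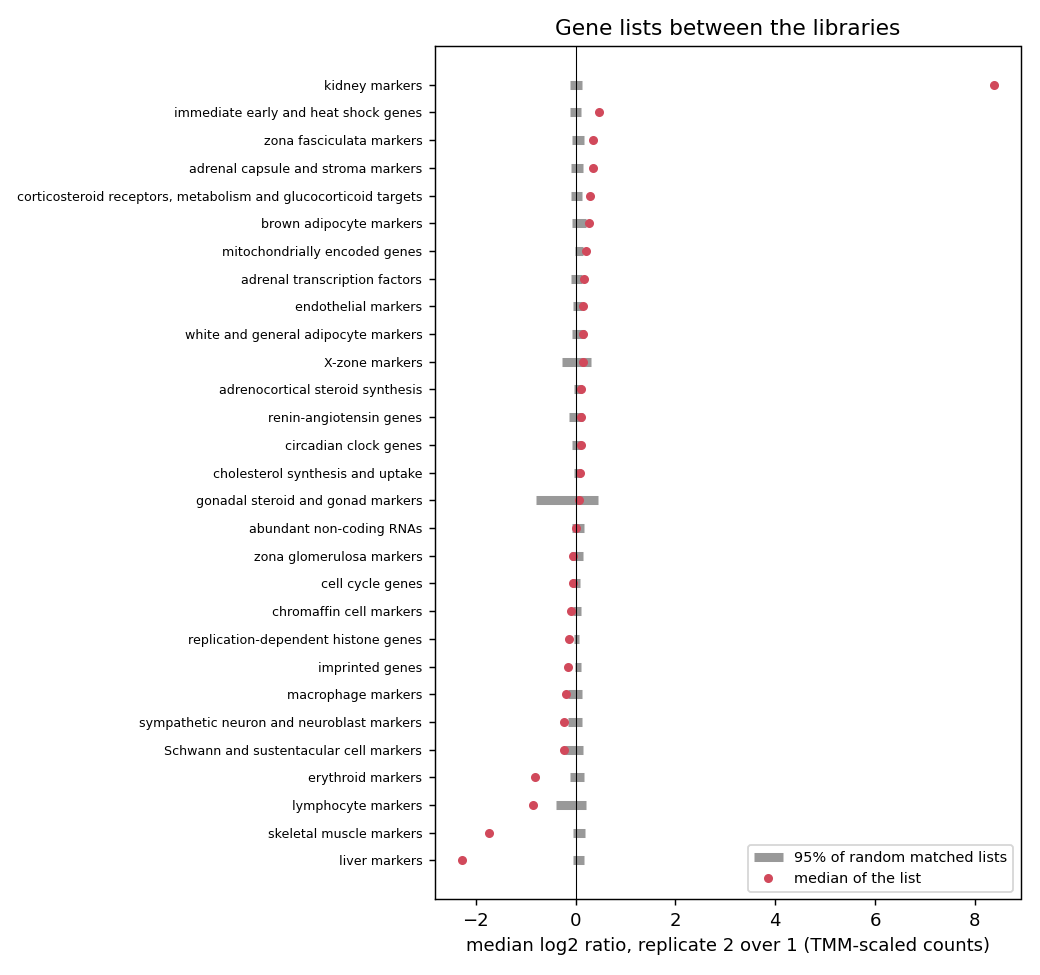
Median log2 ratio of each list, replicate 2 over replicate 1, as points, with grey bars for the central 95% of 10000 random matched lists. The kidney list lies at 8.38 and the liver list at -2.28, while the steroid synthesis list lies at 0.11.

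Over all genes, 1265 of 18883 passed the threshold, 752 higher in replicate 1 and 513 higher in replicate 2. Without the 2-fold limit, 4960 of the 18883 genes lay beyond counting error by the exact binomial test after adjustment. With a negative binomial test that uses the common dispersion 489 genes passed, 227 higher in replicate 1 and 262 higher in replicate 2. That dispersion came from the same 2 libraries taken as 1 group, so this test has no independent replicate check either. The 10 genes with the largest ratios toward replicate 1 were the slow muscle and heart genes Myl2, Myl3, Sln, Myh7, Tnni1 and Tnnt1 together with Smtnl1, Tnnc1, Myoz2 and Hspb7. They ranged from Myl2, 37.9-fold higher (95% interval 25.3 to 59.4), to Hspb7, 12.9-fold higher (95% interval 10.0 to 16.9). Toward replicate 2 they were the kidney transporter genes Slc22a6, Slc34a1, Slc12a1, Slc5a12 and Slc22a12, with Tmem174, Tmem52b, Kif12, Cdh16 and the histone gene Hist1h2ao. Slc22a6 had 0 counts in replicate 1 and was at least 179-fold higher in replicate 2 when replicate 1 is set to the limit of 3 counts, and the lower bound of its exact 95% interval was 145. Hist1h2ao has near-identical copies, so its 0 counts in replicate 1 are uncertain, and its credibility intervals of TPM overlapped, from 5.33e-05 to 21.5 in replicate 1 and from 0.0109 to 45.7 in replicate 2. In 19 of 29 lists the median lay outside the central 95% of random lists. Among these were lists with 0 calls and small medians, such as the chromaffin, endothelial and brown fat lists at -0.08, 0.16 and 0.27. Random lists drew each gene separately, so a small shift shared by the genes of a list can lie outside. In each of the 29 lists the number of calls adjusted over the list alone equalled the number adjusted over all genes.

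**Figure D3:**
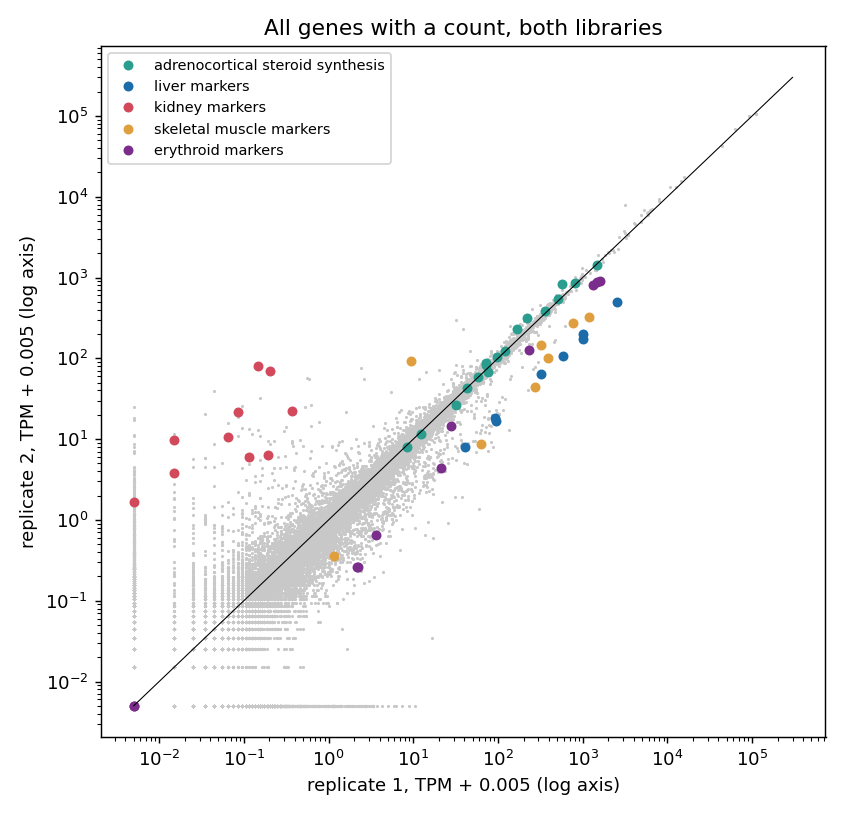
TPM plus 0.005 of all genes with a count, replicate 1 on the horizontal and replicate 2 on the vertical log axis, with a line at equal values and 5 lists in colour. Kidney genes such as Slc34a1 lie far above the line and liver genes such as Alb below it.

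The 2 quantifications differed for short RNAs, with a median log2 ratio of 5.67 over compared genes shorter than 400 nt. Rn7s1 and Rn7s2 were each at 108026 TPM in the gene table and 0.729 TPM in the other quantification, Rn7sk at 43752 and 5.34 TPM, and Rmrp and mt-Atp8 at 6243 and 6132 TPM against 0. In the opposite direction Gm28439, Gm47283 (on chromosome Y in the annotation) and Hist1h2ba were listed at 0 in the gene table. They were at 502, 163 and 141 TPM in the other quantification. AA474408 stood at 0.82 and 0.76 TPM in replicates 1 and 2 against 32.8 and 301 TPM in the other, and Gm8797 at 2.29 against 166 TPM. For genes of at least 400 nt the median log2 ratio of the gene table over the other quantification was -0.59, and for nuclear protein-coding genes it was also -0.59. Star and Hsd3b1 were listed at 1190.2 and 2174 TPM in the other quantification. Pearson's r across genes was 0.842 in replicate 1 and 0.841 in replicate 2, Spearman's rho 0.887 and 0.888, and for nuclear protein-coding genes r was 0.972 and 0.973. Of 8397 genes with at least 10 TPM in either quantification in both libraries 336 differed by at least 4-fold in both libraries, 240 of them higher in the gene table and 96 higher in the other. Of the 240 genes 184 were shorter than 400 nt. Rn7s2 lies on chromosome 12 from 69361182 to 69361481, and Rn7sk on chromosome 9 from 78175303 to 78175633.

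**Figure D4:**
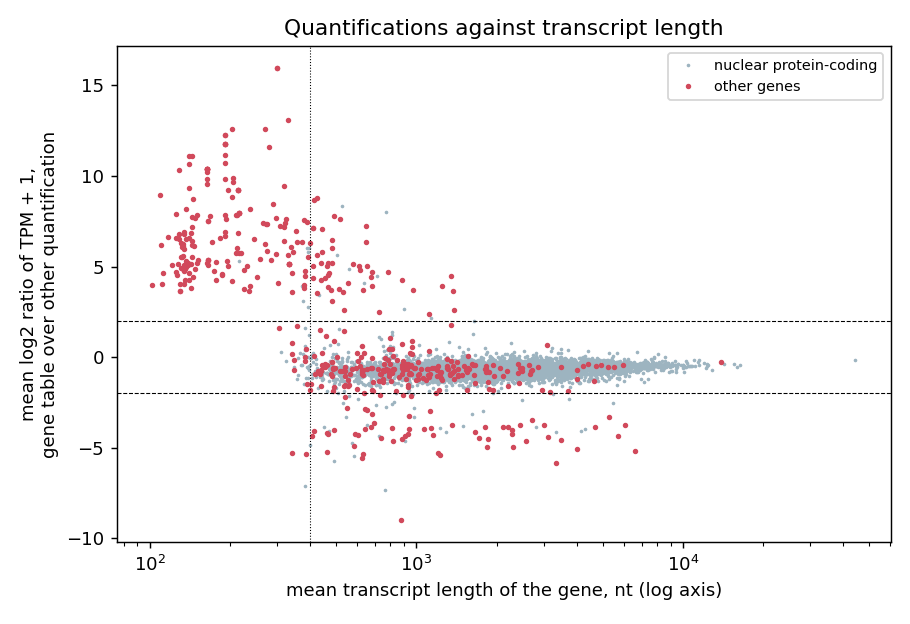
Mean log2 ratio of TPM + 1, gene table over other quantification, against the mean transcript length of each gene on a log axis, with dashed lines at 4-fold and a dotted line at 400 nt. Of the genes higher in the gene table by at least 4-fold, 184 of 240 lie left of the dotted line.

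The dominant transcript of a gene depended more on the quantification than on the library. For Hsd3b1 it was Hsd3b1-201 in the gene table's quantification, with 61.0% and 63.1% of the gene in replicates 1 and 2, and Hsd3b1-202 in the other, with 64.7% and 61.6%. Nr5a1 had Nr5a1-201 in the first and Nr5a1-202 in the other, and Ddc had Ddc-202 and Ddc-210. For Tspo the other quantification named a different transcript in each library. Of 12038 detected genes with several transcripts 89.0% had the same dominant transcript in both libraries, against 86.5% in the other quantification. Between the quantifications it was the same for 74.5% of genes in replicate 1 and 74.7% in replicate 2, and 66.1% had it in both libraries and both quantifications.

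ERCC spike-ins took 0.954 ± 0.0355% of the counts (SD, n = 2), with 0.979% in replicate 1 and 0.929% in replicate 2, a log2 ratio of -0.08. Of 96 sequences 64 had counts in both libraries. With spike-in scaling the median log2 ratio of all genes differed from that with TMM by 0.01. Under this scaling the liver list had a median of -2.28 and the steroid synthesis list, with Star and Hsd3b1, a median of 0.12.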

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

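The features with a bare number as ID take part in no comparison, and a signal in them was looked for against the 3 counts that a count of 0 allows. They held 7 expected counts in replicate 1 and 6 in replicate 2, spread over 26248 features. No explanation was tested.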

How the results depend on the processing

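No paired analysis was possible because there is only 1 group. Comparisons between the libraries cannot leave a library out. The mitochondrial ratio has no value where mitochondrial genes are removed. The restriction to protein-coding genes outside the mitochondrial genome, the credibility intervals and the rescaled quantifications were chosen after seeing the data.

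The counts of detected genes, list genes at 10 TPM, lists with a median of at least 1 TPM, positive paired ratios and lists outside the random range stayed within 1.5 times their values under every alternative run, with 9515 to 20391 genes detected. Levels themselves moved: in the other quantification 60 of 129 named gene levels were over 1.5 times higher and 6 over 1.5 times lower, with Agtr1a at 93.7 TPM, Cyp11b2 at 58.2, Star at 1190.2, Cdh5 at 138 and Hist1h4h at 843, and 13 of 31 list medians were over 1.5 times higher and 1 lower. In the other quantification the median was 1.49 times as high over named genes and 1.47 times over list medians. The limit of 1.5 lies at about this median shift, so these counts do not separate a common rescaling from changes of single genes. Without spike-ins and mitochondrial genes levels were 1.32 times as high at the median and with FPKM 0.941 times, and none moved by over 1.5 times. With each library alone 14684 to 14948 genes were detected. Without replicate 1, 9 of 129 named gene levels were over 1.5 times higher and 15 over 1.5 times lower, as were 2 and 4 of 31 list medians. Without replicate 2 these were 10 and 12 gene levels and 3 and 2 list medians. Among values that passed a threshold Hist2h3c1 changed sign, to -0.22 in the other quantification, where Hist1h4n and Hist1h2ao had too few counts to compare. At 4-fold 9 named genes no longer passed, and in the other quantification 2 more passed, Rn7sk at -2.29 and Gm10925 at 1.54. The count of 1265 genes beyond counting error between the libraries became 489 with the negative binomial test, 599 at 4-fold and 580 at a summed count of at least 200, where fewer genes are tested. It was 1265 with DESeq2 and with ERCC scaling, 1320 with total count, 1100 for protein-coding genes and 1038 with credibility intervals.

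With total count scaling, which shifts all genes, the medians became 0.040 for steroid synthesis, -0.15 for chromaffin, -0.89 for erythroid, 8.31 for kidney, -2.35 for liver and -1.80 for skeletal muscle genes. With the other quantification the kidney and muscle medians were 7.12 and -1.79. Pearson's r between the libraries was 0.976 with a pseudocount of 0.1, 0.983 without a filter and 0.976 in the other quantification. The biological coefficient of variation was 0.293 without a filter and 0.255 in the other quantification. Genes that differ between the quantifications numbered 967 at 2-fold and 571 at 1 TPM. With rescaled quantifications 349 were higher in the gene table and 135 in the other. With a pseudocount of 0.1 Pearson's r between the quantifications was 0.732 and 0.734. Dominant transcripts were the same between libraries for 92.5% of genes at 10 TPM and 98.1% where the transcript held at least 60%, and in both quantifications for 67.5% and 83.6%. The spike-in share was 1.33% of TPM and 0.737% in the other quantification. Where the alternative does not itself tighten a limit, the cause was not tested. Depth limits genes near 3 counts, such as Umod, Slc12a1 and Nphs1 in replicate 1.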

Other observations

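The tests of scaling and of a wrong label, and that of a low mt-Co2 level, were chosen only after the result was seen. Genes in the next 2 paragraphs that no list rule names were chosen after their values were seen.

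Eef1a1, a translation factor gene, was at 2032 ± 7.5 TPM (SD, n = 2), the ATP synthase gene Atp5b at 1857 ± 47.3 TPM, the respiratory chain genes Cox6b1 and Cox4i1 at 1164 ± 113 and 999.9 ± 58.4 TPM, and the alcohol dehydrogenase gene Adh1 at 926 ± 21.4 TPM.

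Muscle and red cell genes did not share a single ratio. Myh1 and Myh8 were 5.79-fold and 6.89-fold higher in replicate 1, whereas Myh4 was 9.40 TPM in replicate 1 and 92.7 TPM in replicate 2. Of 12 other muscle genes listed before their values were seen, 9 passed the threshold toward replicate 1, with a median log2 ratio of -1.44 over all 12. The others, Pygm at -0.96, Actn3 at -0.01 and Mybpc2 at 0.29, did not pass. Slc4a1 of the red cell membrane was 4.45-fold higher in replicate 1, against 1.70-fold for Hba-a1.

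Liver genes were higher in replicate 1. Unequal depth or scaling is argued against, since a factor common to all genes would move the lists alike, and the liver median lay at -2.39 relative to that of the steroid synthesis list. A candidate explanation is liver RNA in different amounts: 19 other liver genes, listed before their values were seen, had a median of -2.29, and all 19 were higher in replicate 1, but 3 of them, Cps1 at -1.18, Apoc3 at -1.23 and Afp at -3.29, lay more than 0.5 from that median, so a single ratio does not cover them. All 8 list genes reached 1 TPM in both libraries, with Alb at 2509 and 502 TPM, and 0 of the 8 list genes belong to another list. How such RNA came to be there stays open, as does a difference between animals, if the libraries came from separate ones, and both were untested.

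Kidney genes were higher in replicate 2. A wrong tissue label is argued against, since the median of the steroid synthesis list was 0.11. Kidney RNA in replicate 2 may account for the pattern: 14 other kidney genes, listed before their values were seen, had a median of 8.31, or 6.89 with genes at 0 counts set to the limit of 3 counts, and all 14 were higher in replicate 2, though 10 lay more than 0.5 from that median, with Slc26a4 at 1.20. In replicate 1, 0 of the 10 list genes reached 1 TPM, and in replicate 2 Slc34a1 and Kap reached 80.8 and 70.2 TPM. A difference between animals, if the libraries came from separate ones, stays open and untested.

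The mitochondrial mRNA mt-Co2 was listed at 160.3 ± 18.4 TPM, against a median of 4564 and 5316 TPM for the 12 other mitochondrial mRNAs in replicates 1 and 2, and in the other quantification at 1477 and 1367 TPM against a median of 4846 and 5535 TPM. Its nuclear copy Gm28661 on chromosome 1, from 24614885 to 24615565, is 100% identical over 99.6% of mt-Co2 and was listed at 16555 ± 1337 TPM. Reads of mt-Co2 may have been given to the copy, and 3 of the 12 others have such copies too, among them mt-Co3, which at 4385 TPM was below its own copy Gm28437 at 7952 and 8825 TPM, and mt-Atp6, which with its copy Gm10925 stood at 5853 and 10835 TPM in replicate 1 of the gene table and at 19520.4 and 341 TPM in the other quantification, so the split depends on the quantification. Together mt-Co2 and the copy came to 3.32 times that median in the lower of the libraries, which cannot exclude a low mt-Co2 level, since the origin of reads from identical sequence is unknown. The 2 explanations cannot be told apart with these tables.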
